A study of Mus musculus with 58 samples.

How the data were processed

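H3K27ac was measured by STAR ChIP-seq in full-grown mouse oocytes of 2 genotypes, with an antibody against H3K27ac. Per the labels, both replicates of a genotype share 1 processed file, so each deposited track is a pool. The tracks give RPKM per bin of 100 bp, computed by the authors, with empty bins left out. That the unit is RPKM was inferred from the deposited values, which sum to what RPKM over such bins must sum to. The submitters' processing notes name the mouse build mm9 and Bowtie2 2.2.2. Read extension, duplicate removal, removal of repeats and use of an input are not given in the sources used here, and any of them could change the values at repeats and pile-ups.

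Every value in both tracks was a whole multiple of the value of 1 read within a tolerance of 0.005 RPKM. This read value was 0.326 RPKM in control and 0.341 RPKM in knockout, and the reads recovered from it were 30694806 in 11679676 bins in control and 29367645 in 8718653 bins in knockout. Reads were uneven inside windows, with a variance over that of independent counts of 2.37 in control and 4.28 in knockout. Bins with even read numbers made up 43.0% in control and 52.9% in knockout. Intervals from counts cover counting error only and are too narrow for these reads.

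Signal was averaged over 5 kb windows of the autosomes and X. Windows whose mean over both pools was at or above the genome-wide mean were compared as the log2 ratio of knockout over control of RPKM + 0.1, a scale that understates changes of low windows, and called at 2-fold. With pooled tracks there was no test and no p-value. Named windows were the 5 highest and 5 lowest log2 ratios past the filter, at least 1 Mb apart. Domains were adjacent windows at or above 3 times the mean of their own pool. Ratios of single windows have exact binomial (Clopper-Pearson) intervals at 95%, shares of reads have Wilson intervals, and a bootstrap of 500 draws over 1 Mb blocks was used for correlations and for X against autosomes. The groups, the main rules and most alternatives were chosen before the data were examined. The alternatives were other pseudocounts, scalings, filters, fold rules, window sizes and domain thresholds, and for the class means a median. Windows of 100 kb, at most 10 reads per bin and autosomes alone were added afterwards, and so were the 1 Mb blocks, the runs of changed windows, the comparison of X with autosomes at equal control level, the segment of chromosome 2 and the ranking of windows on alternate blocks.

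The code was tested on simulated data. The reads of 100% of simulated bins were recovered in both pools. This comparison was simulated over 527788 windows of 5 kb. Known folds were given to a small set of them, drawn only from windows at or above the genome-wide mean. Of these changed windows, the 2-fold rule called 6.00% at a true fold of 1.5, 83.0% at a fold of 3 and 93.5% at a fold of 4.

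The plan also included promoters, gene bodies, the Setd2 locus and 11 gene lists with 248 entries. These need an annotation of mm9 and were not analysed here, so regions are given by coordinate and no gene is named for them. Numbers of protein-coding genes per chromosome came from a RefSeq table of the GRCm38 assembly, from which no position was used. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.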

Results

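The series profiled histone modifications in mouse oocytes and early embryos by STAR ChIP-seq, a chromatin immunoprecipitation method for small numbers of cells. It holds 58 samples in 34 groups. The comparison analysed here concerns acetylation of histone H3 at lysine 27 (H3K27ac), a modification found at active promoters and enhancers, in full-grown oocytes. Oocytes labelled Setd2+/- served as the control, and oocytes labelled Setd2-/- came from a maternal knockout of Setd2, which encodes a methyltransferase that places H3K36me3. Each genotype had 2 replicates, and the authors pooled them into 1 track per genotype. All values below are therefore the authors' pooled values in RPKM, a read density scaled to the length of the bin and the size of the library, no spread between replicates was measurable, and no test was made. The control pool held 30694806 reads and the knockout pool 29367645 reads, as recovered from the step between values. The remaining 54 samples were not analysed here. The question was where the H3K27ac landscape of the oocyte differed when Setd2 was lost, as the series' design sets knockout oocytes against controls to relate histone modifications to one another.

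Relative to library size, chromosome X carried less H3K27ac in the knockout pool than in the control pool. Its mean fell from 0.455 to 0.258 RPKM, a ratio of 0.566, whereas the ratios of the 19 autosomes lay between 0.901 on chromosome 3 and 1.19 on chromosome 11. Among the autosomes and X, X had the highest mean in the control pool, at 1.22 times the autosomal mean, and the lowest in the knockout pool, at 0.666 times the autosomal mean. It held 7.59% of control reads (95% Wilson interval 7.58 to 7.60) and 4.30% of knockout reads (4.29 to 4.30). Relative to the autosomes, the knockout over control ratio of X was 0.547 (0.546 to 0.548 from counting error). These intervals cover counting error only, and reads were more uneven than independent counts would be, so they are too narrow.

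**Figure D1:**
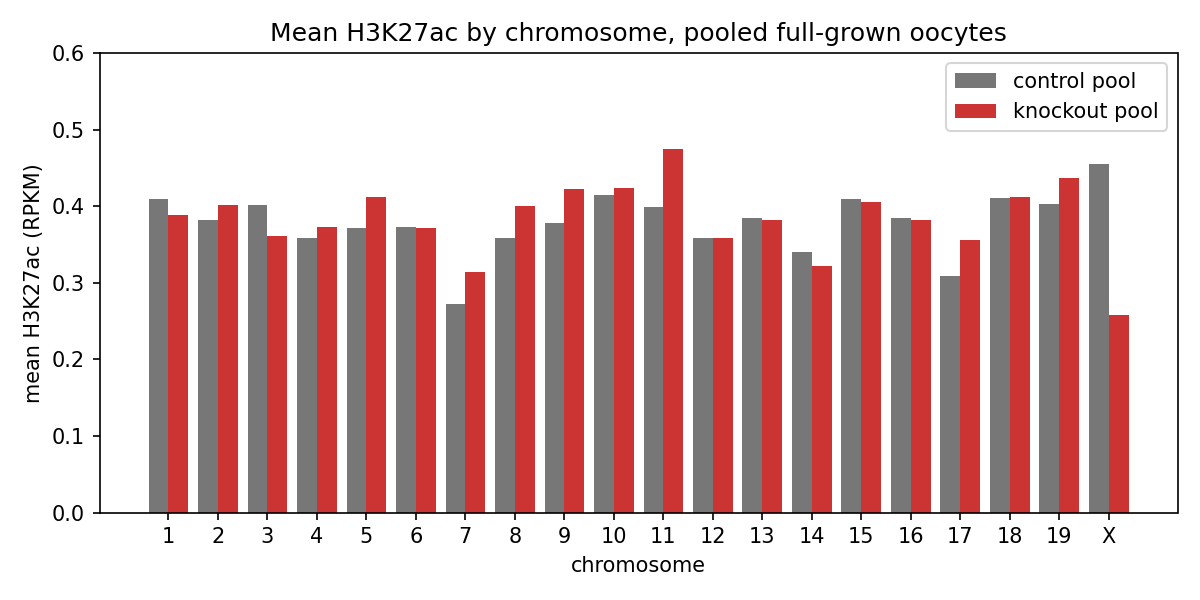
Mean H3K27ac per chromosome (RPKM, vertical axis from 0) in the authors' pooled control track (grey bars) and pooled knockout track (red bars), without error bars because no replicate values were used. X fell from 0.455 to 0.258 RPKM, and chromosome 11 stood at 0.399 RPKM in control and 0.475 RPKM in knockout.

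The lower signal extended along most of X. Of 157 blocks of 1 Mb on X, 142 were lower in the knockout pool and 68 were at least 2-fold lower, with a median ratio of 0.562. The ratios of X blocks ran from 0.203 to 2.56, and 6 blocks were at least 2-fold higher, all of them poor, with 0.0241 to 0.0410 RPKM in control and 0.0552 to 0.105 RPKM in knockout. On the autosomes, 1106 of 2376 blocks were lower, 144 were at least 2-fold lower and 80 were at least 2-fold higher, with a median ratio of 1.04. The difference on X varied with the control level, and was largest at middle levels. Among 10 kb windows with 0.5 to 0.6 RPKM in control, the median knockout signal on X was 0.420 of that of autosomal windows of the same control level (95% bootstrap interval over 1 Mb blocks of X, 0.384 to 0.460). It was 0.713 (0.650 to 0.783) among windows with 1 to 1.5 RPKM in control, 0.706 (0.647 to 0.765) among those with 0.05 to 0.1 RPKM and 0.630 (0.519 to 0.704) among those with 0.02 to 0.05 RPKM.

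**Figure D2:**
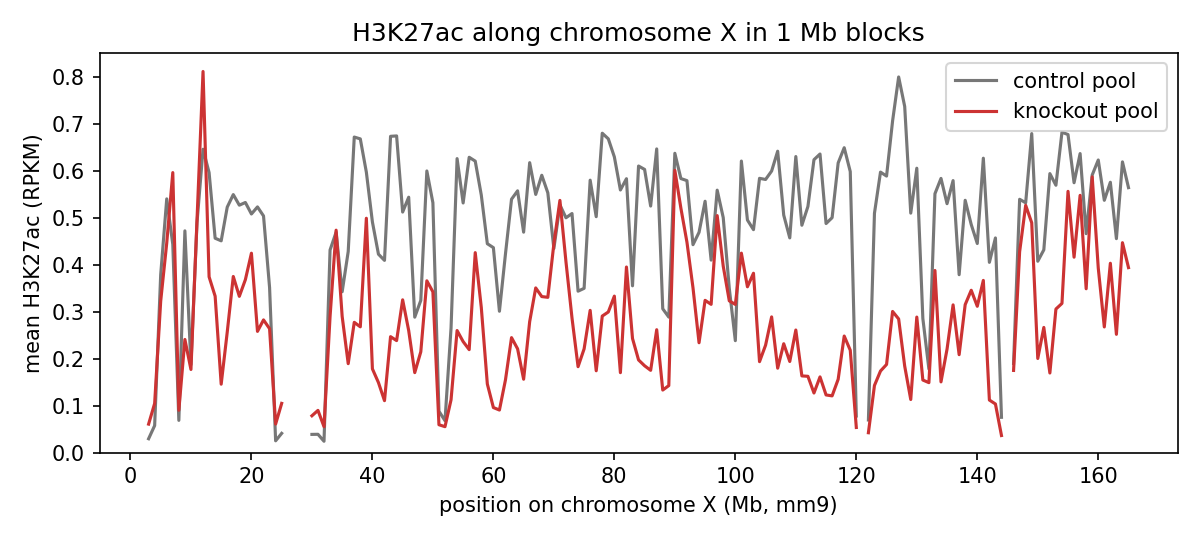
Mean H3K27ac (RPKM) along chromosome X in 1 Mb blocks by position (Mb, mm9), with the control pool in grey, the knockout pool in red, and gaps where blocks held almost no reads. The knockout line lies below the control line in 142 of 157 blocks.

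Chromosomes 11, 7, 17, 9, 8, 5 and 19 had more H3K27ac in the knockout pool, with ratios of 1.19, 1.16, 1.15, 1.12, 1.11, 1.11 and 1.08. Chromosome 11 went from 0.399 to 0.475 RPKM and chromosome 7 from 0.272 to 0.315 RPKM. Chromosome 3 went the other way, from 0.401 to 0.361 RPKM. These 8 chromosomes kept their direction under each of 3 other scalings of the tracks, and so did chromosomes 2, 4 and 10. None of these scalings set the autosomal means equal, which were 0.374 RPKM in control and 0.387 RPKM in knockout. As RPKM is scaled to library size, fewer reads on X raise the values of the autosomes, and more reads on the autosomes lower that of X. The tracks therefore give X and autosomes relative to each other, and absolute levels of H3K27ac cannot be read from them. Chromosomes 4 and 10, with ratios of 1.04 and 1.02, lay below the unweighted mean of the autosomal ratios, 1.043. The ratio of the autosomal means was slightly lower than that, and chromosome 4 lay between them. Its direction against the other autosomes thus depends on which is used, whereas chromosome 10 lay below both. The other 8 autosomes, chromosomes 1 and 14 among them, had ratios from 0.947 to 1.00 whose direction differed between scalings. X stayed below 1 under each scaling, between 0.556 and 0.610.

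In windows of 5 kb, H3K27ac differed at least 2-fold at many places in both directions. Of 217733 windows at or above the genome-wide mean of 0.379 RPKM, 25170 (11.6%) were at least 2-fold higher in the knockout pool and 33034 (15.2%) at least 2-fold lower. At least 4-fold differences numbered 1407 higher and 3833 lower. X contributed 6.12% of the windows compared, 17.0% of the lower ones and 1.00% of the higher ones. On X, 5600 of 13333 windows were lower and 252 were higher, with a median log2 ratio of -0.80. On the autosomes, 27434 of 204400 windows were lower and 24918 were higher, with a median log2 ratio of 0.07. In a simulation of pools that did not differ, with the unevenness of reads measured inside each pool, 509 windows were higher and 409 lower on average over 10 draws. That simulation holds no differences between animals or between libraries, such as in background or in the efficiency of the precipitation, which could not be measured. Its counts are therefore a comparison with uneven counting only. The surplus of lower over higher windows turned with the settings: scaling on the poorer windows gave 31346 higher and 27929 lower, and a filter at 2 times the mean gave 10621 higher and 2555 lower.

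**Figure D3:**
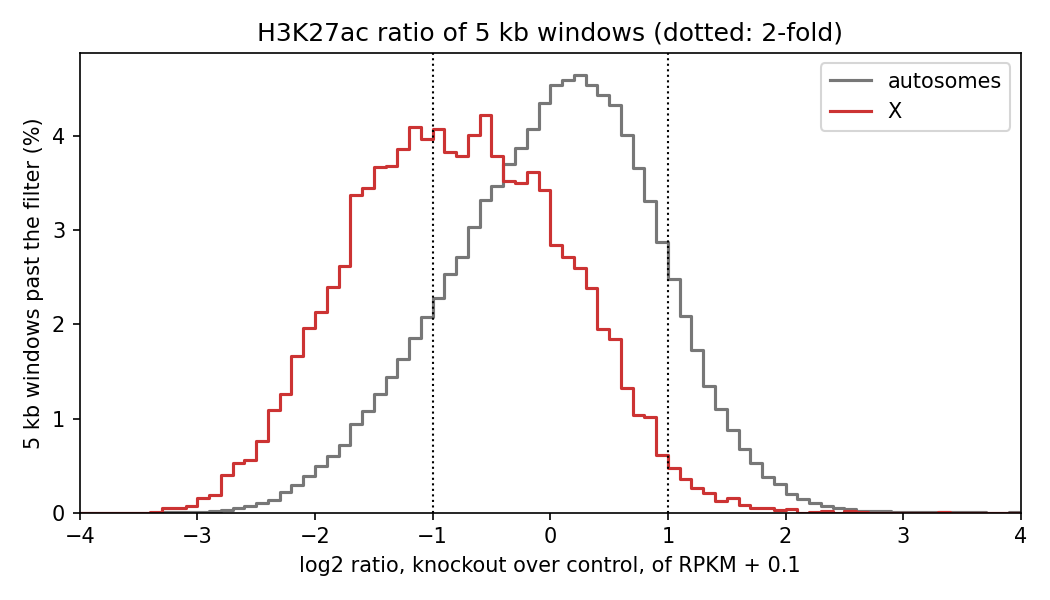
Distribution of the log2 ratio of knockout over control (RPKM + 0.1, horizontal axis) as percent of 5 kb windows past the filter (vertical axis) for autosomes (grey) and X (red), with dotted lines at 2-fold. The median lies at 0.07 on autosomes and at -0.80 on X, and 42.0% of X windows were at least 2-fold lower.

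The windows with the lowest ratios had H3K27ac well above the mean in the control pool and almost none in the knockout pool. The high control level follows from the filter, which keeps a window almost empty in 1 pool only if the other pool is well above the mean. Counting intervals of the lowest and highest windows do not allow for their choice as extremes. On X, the window at 143960001 to 143965000 (mm9, as all coordinates here) had 147 control reads and 1 knockout read, or 0.958 and 0.00681 RPKM, a log2 ratio of -3.31. Its control signal was 141 times the knockout signal, with a 95% counting interval of 24.9 to 5592. On chromosome 15, the window at 63015001 to 63020000 had 145 and 1 reads, a ratio of 139 (24.5 to 5516). The next were on chromosome 12 at 91360001 to 91365000, with 151 and 2 reads, on chromosome 1 at 8620001 to 8625000, with 169 and 4 reads, and on X at 128800001 to 128805000, with 149 and 2 reads. Their log2 ratios were -3.25, -3.24 and -3.24.

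The windows with the highest ratios were led by chromosome 2 at 77735001 to 77740000, where the control pool had 20 reads and the knockout pool 1317. Its knockout signal of 8.97 RPKM was 68.8 times the control signal (95% counting interval 44.4 to 113), a log2 ratio of 5.30. The window on chromosome 6 at 136350001 to 136355000 had 16 and 465 reads, a 30.4-fold difference (18.5 to 53.6) and a log2 ratio of 4.00. The other 3 had most or many of their reads in single bins of 100 bp. On chromosome 9, the window at 2995001 to 3000000 had 100% of its knockout reads in 1 bin, and the window at 91255001 to 91260000 had 98.7%. On chromosome 2, the window at 98505001 to 98510000 had 23.8% of 31486 knockout reads in 1 bin. Their log2 ratios of 3.69, 3.68 and 3.67 became 0.03, 0.64 and -0.23 with at most 10 reads counted per bin. The same limit lowered the leading window of chromosome 2 from 5.30 to 3.85 and that of chromosome 6 from 4.00 to 2.92. A further ranking, chosen after the values were seen, left out windows with over 20% of 30 or more reads in 1 bin and windows at 10 times the genome-wide mean or more in either pool. The leading window of chromosome 2 had 4.56% of its knockout reads in its richest bin and was left out for its level alone. This ranking put chromosome 2 at 77710001 to 77715000 first, with 4 and 465 reads, and kept the window of chromosome 6. It brought up chromosome 10 at 69650001 to 69655000, with 20 and 361 reads, and chromosome 5 at 112610001 to 112615000, with 8 and 230 reads. It also brought up X at 166580001 to 166585000, with 2 and 152 reads, a window 79.4-fold higher in knockout (21.6 to 662) on the chromosome that was lower as a whole. This window of X had 19.7% of its knockout reads in 1 bin, just under the limit of 20%, and both control reads in 1 bin. It lay near the end of X, at 166650296, past the last of the 1 Mb blocks.

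The leading window of chromosome 2 lay in a longer segment, which was delimited after its values were seen. From 77707001 to 77865000, over 158 kb, the mean was 0.292 RPKM in control and 5.98 RPKM in knockout, a 20.5-fold difference. In the 100 kb on either side the means were 0.114 and 0.123 RPKM. The knockout signal went from 0.0681 RPKM in the last 1 kb before the segment to 1.98 RPKM in its first, and from 4.94 to 0.443 RPKM at its other end. The segment held 27722 knockout reads, 0.0944% of the pool.

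**Figure D4:**
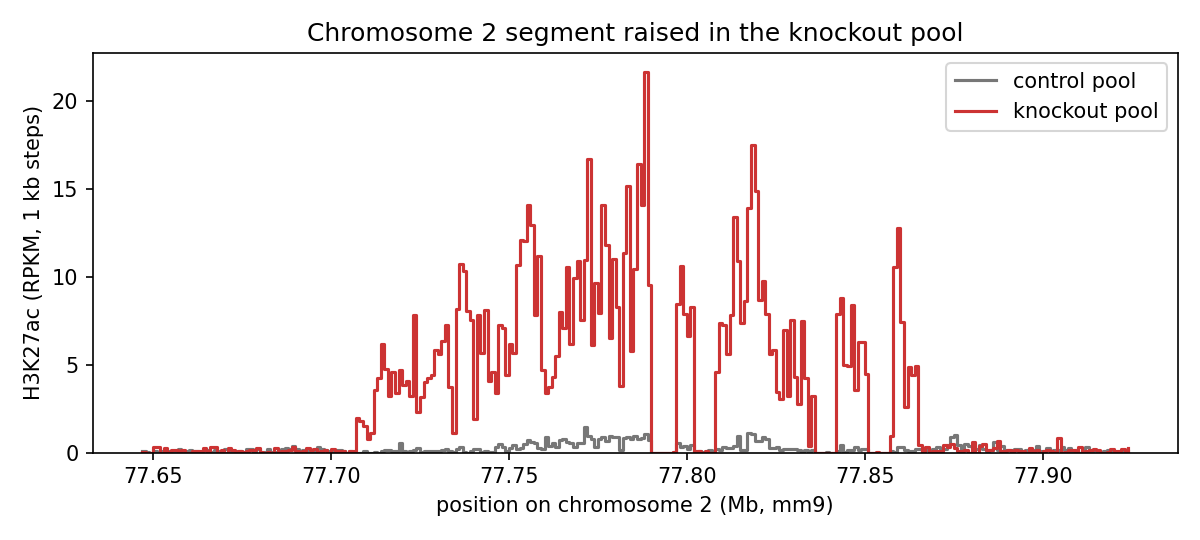
H3K27ac (RPKM, 1 kb steps) by position on chromosome 2 (Mb, mm9), with the control pool in grey and the knockout pool in red. The knockout pool averaged 5.98 RPKM between 77707001 and 77865000 and 0.123 RPKM in the 100 kb on either side, and both lines are at 0 in stretches inside the segment.

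Changed windows also formed longer runs. Runs of any length, single windows included, numbered 14274 for higher and 20182 for lower windows. Runs of higher windows of 50 kb or more numbered 87 and runs of lower windows 39. The longest higher run, on chromosome 18 from 38700001 to 38835000, went from 0.489 to 1.49 RPKM, a 3.05-fold difference over 135 kb. On chromosome 16, the run from 22015001 to 22125000 went from 0.345 to 1.14 RPKM. The longest lower run, on X from 80340001 to 80415000, went from 0.959 to 0.290 RPKM over 75 kb. Chromosome 4 had a lower run of 70 kb from 108155001 to 108225000, where the mean was 0.961 RPKM in control and 0.273 RPKM in knockout. Of 393 lower runs of 30 kb or more, 103 lay on X, against 2 of 471 higher runs.

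H3K27ac-rich domains, set at 3 times each pool's own mean, were more numerous in the knockout pool. Their median length was 5 kb in both pools, the length of 1 window. Reads were more uneven inside windows in knockout, with a variance over that of independent counts of 4.28 against 2.37 in control. How far this unevenness adds to the number of domains was not tested. The control pool had 7966 domains that covered 48.7 Mb and held 6.27% of its signal, and the knockout pool had 17601 domains over 158 Mb with 22.9% of its signal. Rich windows made up 4.07% of X in control and 2.47% in knockout, while on the autosomes they rose from 1.70% to 6.21%. Of the control domains, 2237 (28.1%) overlapped a knockout domain, against 6.54% on average when the knockout track was rotated along each chromosome 20 times. Rich windows in both pools numbered 2487, 4.27 times the number of independent sets. At 2 times the mean the order turned, with 37246 domains in control and 31414 in knockout.

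The landscapes of both pools were compared over 5 kb windows. Pearson's r of log2(RPKM + 0.1) was 0.716 across all 5 kb windows (95% bootstrap interval over 1 Mb blocks, 0.708 to 0.725) and Spearman's rho 0.712, where windows are not replicates. Over the windows at or above the genome-wide mean, the set used for the 2-fold calls, r was 0.00018 and rho 0.0466, values lowered by construction because that filter removes windows low in both pools. On X alone r was 0.698 and on autosomes 0.726. Within a pool, alternate stretches of bins of the same windows correlated at 0.922 for control and 0.860 for knockout. These stretches share animals and libraries, so the values do not say how replicate libraries would correlate.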

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

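All tests in this part were chosen after the results were seen.

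Chromosome Y was outside the comparisons and held 927 reads in the knockout pool and 274 in the control pool. Scaled to library size in RPM these were 31.6 and 8.93, and what flagged them is that the knockout level lies above that of the control. The mean over the part of Y with reads was 2.84% of the autosomal mean in knockout and 0.831% in control.

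The lower H3K27ac on X was weighed against 3 technical explanations. DNA of male cells would raise Y towards the level of X if Y carried H3K27ac as X does, which was not tested. In the knockout pool the mean over the part of Y with reads stood at 2.84% of the autosomal mean. A uniform loss of X DNA as the whole cause would leave X windows at 1 share of autosomal windows of equal control level, but the highest share was 1.70 times the lowest, against at most 1.42 times for any of the 19 autosomes, and 2.62 against at most 1.84 when matched on knockout with such a loss undone. The ratio of autosomes rose with their density of protein-coding genes (Pearson's r 0.847, Spearman's rho 0.830 over 19 autosomes, r 0.766 without the 2 farthest in density), yet X lay 9.19 residual SD below that line. A partial loss of X DNA, or differences between the pooled animals, may still contribute, and loss of Setd2 remains a hypothesis that these pools cannot test.

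The segment of chromosome 2 was weighed against a narrow pile-up and extra DNA copies. The richest 1% of its bins held 5.05% of its knockout reads, far below what a narrow pile-up would give. Extra copies would raise windows poor and rich in control by 1 factor only if knockout over control were otherwise equal in both. Over the autosomes it was not. Among autosomal windows of 10 kb ranked by control, this ratio was 2.51 in the lowest of 10 classes and 0.890 in the highest. In the segment, the pooled factors were 40.2 for 15 poor windows and 16.4 for 15 rich ones, a quotient of 2.45. The quotient was 2.09 when poor and rich were called on alternate 1 kb blocks and the factors measured on the others. Thus 1 factor for all windows was not met, but given the trend over the autosomes this cannot decide against extra copies. Extra copies stay possible, with or without differences in H3K27ac along the segment, as does a local gain of H3K27ac. No input track was used here to separate them.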

How the results depend on the processing

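No paired analysis was possible because each file pools both replicates of a genotype, and for that reason leaving out a replicate was not run either. Alternatives for promoters, gene lists, gene classes and the Setd2 locus were not run, as no annotation of mm9 was used here. Windows of 100 kb, at most 10 reads per bin and autosomes alone were chosen after seeing the data. The 2-fold windows, 25170 higher and 33034 lower (43.2% higher), were within 1.5 times of those counts under the 3 scalings, a pseudocount of 0.01, without the richest 0.1% of windows, with at most 10 reads per bin and on autosomes alone. Background scaling multiplied the knockout signal by 1.08, a shift of 0.11 on the log2 scale that is smaller in windows low in knockout because of the pseudocount, and turned the share of higher windows to 52.9%, and a filter at 2 times the mean turned it to 80.6%, with 10621 higher and 2555 lower. The latter filter keeps only windows rich in at least 1 pool. The former raises every knockout value by 1 factor, so by construction more windows reach the limit for higher and fewer that for lower. The counts higher and lower were 5610 and 6916 with a pseudocount of 0.5 (44.8% higher), 45292 and 68946 with no filter (39.6%), 55365 and 57776 at 1.5-fold (48.9%), 79736 and 95427 in 2 kb windows (45.5%), 10971 and 14799 in 10 kb windows (42.6%) and 489 and 922 in 100 kb windows (34.7%). The counts follow from the number of windows or the rule itself, and for the shares the cause was not tested. The share was 44.2% with a pseudocount of 0.01, 40.8% with the median set to 0, 42.8% without the richest windows, 38.2% with at most 10 reads per bin and 47.7% on autosomes. Pearson's r was 0.664 in 2 kb and 0.733 in 10 kb windows, and 0.00018 over windows at or above the mean, where a filter on the mean of both pools removes windows low in both. Domains in control and knockout, and control domains that overlapped, numbered 37246, 31414 and 20741 at 2 times the mean, 33, 1300 and 16 at 5 times, and 30821, 46988 and 10010 in 2 kb windows. Knockout domains per control domain were 2.21 in the main setting, turned to 0.843 at 2 times the mean, and were 39.4 at 5 times, 1.52 in 2 kb windows and 2.29 with at most 10 reads per bin; the cause was not tested. The ratio of X relative to autosomes, 0.547, was 0.462 by medians over windows and 0.553 with at most 10 reads per bin, below 1 in each setting run. Of 60 values for the 10 named windows, 19 kept their direction outside the counting interval, taken here on the scale of log2(RPKM + 0.1), and 1 turned direction, the window of chromosome 2 at 98505001, at -0.23 with at most 10 reads per bin. The log2 ratio of the window of X at 143960001, -3.31, was -5.85 with a pseudocount of 0.01 and -1.52 with 0.5. Depth limits windows with few reads, where ratios have wide intervals, and the spread between animals was not measurable.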

Other observations

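The test of even background was chosen after its result was seen.

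Windows poor in one pool had a higher mean in the other, which medians showed only in part. Windows of 10 kb on autosomes were ranked by the signal of a pool in alternate 1 kb blocks and measured in the remaining blocks. Ranked by control, the lowest of 10 classes had a mean of 0.0363 RPKM in control and 0.0913 RPKM in knockout, and the highest class 0.894 and 0.795 RPKM. Ranked by knockout, the lowest class had a mean of 0.104 RPKM in control and 0.0787 RPKM in knockout, and the highest class 0.705 and 1.17 RPKM. On X, the lowest class had means of 0.0237 and 0.0478 RPKM when ranked by control and 0.0927 and 0.0431 RPKM when ranked by knockout. The medians of the lowest class were higher in knockout in both rankings. On autosomes they were 0.0261 RPKM in control and 0.0749 RPKM in knockout when ranked by control, and 0.0587 and 0.0681 RPKM when ranked by knockout. On X they were 0.0130 and 0.0204 RPKM, and 0.0196 and 0.0272 RPKM.

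The richest windows held more of the signal in the knockout pool. The richest 1% of 5 kb windows had 3.64% of the signal in control and 5.44% in knockout. If clumps of more than 3 reads in single bins were the whole cause, the excess would vanish with at most 3 reads per bin. The share in knockout was still 1.24 times that in control, against 1.49 times with all reads, so such clumps may account for part of it. That limit leaves doubled reads in place, and bins with even read numbers made up 52.9% in knockout and 43.0% in control. Clumping of few reads as the cause of the rest is therefore not excluded. Even background in the control pool as the cause stays open. It would leave the poorest windows with no more signal in knockout than in control, and the ratio of means was 2.51 when they were ranked by control and 0.758 when ranked by knockout. Each ranking by itself favours the pool that was not ranked. The medians went one way in both rankings, but lay close together when ranked by knockout, and neither measure excludes it. Other differences between the pools, such as the number of oocytes or the efficiency of the precipitation, and a loss of Setd2 remain open and untested.

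Windows at 10 times the genome-wide mean or more numbered 21 in control and 82 in knockout, and 20 were shared.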
